A study of Mus musculus with 2 samples.

How the data were processed

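Total RNA-seq libraries from the left cerebral cortex of 2 female hybrid mice (C57BL/6J and CAST/EiJ) at postnatal day 4 were analysed. Per the labels, RNA was purified with a kit for animal tissue, 300 ng entered each library, and ERCC spike-in RNAs for stranded, ribosomal RNA reduced libraries were added. Both libraries formed 1 group, left cerebral cortex, with the replicate numbers of the labels; each came from its own donor animal. No condition was contrasted, so no test between groups was made.

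Each library had 3 tables: a gene table and a transcript table from the first quantifier, called the first table here, and a transcript table from another quantifier, called the second table. Assembly mm10 and the GENCODE M21 annotation are named per the file descriptions deposited with the tables. The aligner and the versions of the quantifiers are not given in the sources used here. Per the deposited file descriptions, the first table was made from reads aligned to the transcriptome; per the file headers it gives expected counts, in which the authors' quantifier split reads shared between features; the column names are those of RSEM. By the same descriptions the second table was made directly from the reads, and its estimated counts, as deposited, have the column names of kallisto. The deposited TPM values are scaled by effective length in both tables, spike-ins included; the first table takes 99 bases off each length. The deposited FPKM values are scaled by effective length and counted reads, per the file headers, and the percent values deposited with transcripts are the share of the gene's TPM. The posterior standard deviation of each count, as deposited by the authors, was used as a measure of reads shared between features.

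The gene table has 81881 entries: 55536 annotated genes, 96 spike-ins, 1 phiX genome and 26248 entries with a number in place of a gene identifier. Spike-ins, phiX and the numbered entries stayed out of library sizes and gene tests. Gene names, biotypes and coordinates came from GENCODE M21 on GRCm38, and where a symbol belonged to several genes the one with the highest mean TPM was used. Gene counts summed to 29310533 in replicate 1 and 28844674 in replicate 2, and the second table to 29886335 and 29926132. Counting precision at this depth is given as exact 95% Clopper-Pearson intervals of count ratios, and a count of 0 allows up to 3 counts. Variants of the CAST/EiJ genome against the reference were not modelled, and the signal tracks named in the file descriptions were not used here.

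Genes were called detected at a TPM of at least 1 in both libraries. Levels are means with SD (n = 2). Agreement was measured over detected genes on log2(TPM + 1), as Pearson r, Spearman rho and the SD of the log2 ratio. Gene pairs were compared as log2 ratios with a pseudocount of 1 and called apart at a ratio of at least 1 in size with the same sign in both libraries. The biological coefficient of variation came from edgeR 4.0.16 (R 4.3.3) with an intercept only, TMM factors of 0.990 and 1.01, and genes kept by filterByExpr. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used otherwise.

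Genes with a summed count of at least 20 were compared between the libraries by an exact two-sided conditional binomial test on expected counts rounded to whole numbers, with TMM-scaled library sizes and Benjamini-Hochberg adjustment. Calls needed an adjusted p under 0.05 and a log2 ratio of at least 1 in size; log2 count ratios had 0.5 added to each count. Folds printed with intervals are ratios of scaled rounded counts with nothing added. The test covers counting error and compares these libraries, not conditions. For each of 37 gene lists, the median log2(TPM + 1) ratio of members with a mean TPM of at least 1 was placed among 10000 random lists matched on mean expression in 20 bins. Dominant transcripts were those with the highest TPM of a gene with several annotated transcripts.

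Gene lists, pairs, isoform genes, the comparisons of the report and their thresholds were fixed before the data were examined. The tests of explanations in the closing section were written after the levels and differences were seen. Counting intervals and the adjustment over the lists alone were added later. Of the listed symbols, 4 matched no annotated gene. Named were, of each list, up to 4 members with the highest and 2 with the lowest mean TPM; every pair; the 10 most abundant genes; the 10 genes with the largest log2 ratio in each direction at a mean TPM of at least 1; isoform genes whose dominant transcript took at least 50% in both libraries and was the same in both tables, and those whose dominant transcript differed between quantifiers; and members of called lists. Some results that this rule names are not reported here.

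The binomial test and the coefficient of variation were tested on simulated counts, and the list test on random lists drawn from the measured ratios. The binomial test recovered 199 of 200 genes changed 4-fold and called 1 unchanged gene, over 18503 genes, in library 2 against library 1. These simulated counts held counting error only, with equal library sizes, and the changed genes were drawn from better-counted genes. False calls under further spread between libraries, or under reads shared between features, were therefore not measured. Of 100 random lists of 13 genes 4 had a p under 0.05 in the list test, and 100 of 100 lists shifted by 0.5 did, over 15304 genes. The random lists were ranked among lists drawn in the same way, so their rate was largely set by the procedure. False calls among lists of genes that vary together were not measured. The shift of 0.5 was larger than the medians of the called ribosomal protein and histone lists (-0.10 and -0.11). A coefficient of variation of 0.2 was recovered as 0.198 over 17823 genes.

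Alternatives set in advance were other TPM thresholds, the second table, a pseudocount of 0.1, FPKM in place of TPM, DESeq2 1.42.0 size factors, spike-in counts as library size, other count filters, no minimum ratio, an edgeR exact test with the trended dispersion, stricter choices of dominant transcripts and spike-ins, and leaving out each replicate. Added after seeing the data were list differences with the trend with transcript length or GC content removed, random lists from protein-coding genes, the gene comparison without TEC and sense intronic genes, and the gene comparison on counts from the second table. Further erythroid and choroid plexus markers, 24 and 17 genes, were written down before their test but after the levels of the fixed lists were seen.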

Results

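Total RNA was sequenced from the left cerebral cortex of female mice at postnatal day 4. The animals were first-generation hybrids of C57BL/6J and CAST/EiJ, a wild-derived inbred strain. The series held 1 group of 2 libraries, each from a separate donor animal, and no treatment, genotype or tissue was contrasted. The comparisons below therefore describe levels in this tissue and the spread between the libraries. In that spread, the animal and the preparation of its sample and library cannot be separated. Each library was prepared from 300 ng of RNA with synthetic spike-in RNAs added. The gene tables summed to 29407463 expected counts in replicate 1 and 28944700 in replicate 2. A count of 0 at this depth allows up to 3 counts, or 0.102 and 0.104 ppm of the counts of replicates 1 and 2. Levels are TPM values, given as mean ± SD over the libraries (n = 2) unless a library is named, and coordinates are on mm10 (GRCm38). The sources used here name no molecular identifiers on the reads, so intervals and floors cover counting error only.

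Structured noncoding RNAs were at the head of the abundance ranking. Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, were each at 125460 ± 3306 TPM, and Rn7sk, the RNA that holds back the elongation factor P-TEFb, was at 47429 ± 2510 TPM. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 were at 23526 ± 91.1 and 14772 ± 192 TPM. Rpph1, the RNA of ribonuclease P, was at 8213 ± 424 TPM. Tuba1a, an alpha tubulin of developing neurons (ENSMUSG00000072235.6, chromosome 15, 98949837 to 98953703), was at 4249 ± 195 TPM and was the one nuclear protein-coding gene among the 10 most abundant. The other members of the 10 were Gm26917 (20738 ± 397 TPM), Gm42418 (3751 ± 95.3 TPM) and Gm28661 (4576 ± 105 TPM). Gm26917 and Gm42418 are annotated as lincRNAs and lie next to each other on chromosome 17 (39843013 to 39848788). Gm28661 is annotated as an unprocessed pseudogene on chromosome 1. These labels are biotypes of the annotation, and the sequences of the loci were not examined. Whether the reads at the chromosome 17 loci came from ribosomal RNA was not tested. Together the 10 genes held 38.6% and 37.1% of TPM in replicates 1 and 2, but 12.3% and 11.6% of the expected counts. Rn7s1 and Rn7s2 had identical values in each library, so their reads were split evenly and neither level is that of 1 locus.

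By RNA class, nuclear protein-coding genes held 83.4% ± 0.145 of the expected counts (SD, n = 2) but 50.8% ± 0.561 of TPM, because short RNAs weigh more in TPM. The misc_RNA class, which contains Rn7s1, Rn7s2 and Rn7sk, held 4.00% ± 0.217 of counts and 29.9% ± 0.903 of TPM. Mitochondrial ribosomal RNA held 3.09% ± 0.0915 of counts, mitochondrial protein-coding genes 1.13% ± 0.0218, and Gm26917 with Gm42418 4.09% ± 0.172. Small nuclear RNAs held 0.149% ± 0.00660 of counts and small nucleolar RNAs 0.0504% ± 0.00109. The remaining long noncoding genes, together with loci of the TEC biotype, transcribed loci that await experimental testing, held 2.01% of counts in replicate 1 and 2.55% in replicate 2. In the second transcript table, made by another quantifier, misc_RNA held 0.00402% of TPM and small nuclear and small nucleolar RNAs held 0%, so the levels of short RNAs depended on the table.

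At a TPM of at least 1 in both libraries, 15304 of 55536 annotated genes (27.6%) were detected. They included 13137 of 22028 protein-coding genes (59.6%), 478 TEC loci and 293 lincRNAs. Replicate 1 alone had 15719 genes at that level and replicate 2 alone 16420. Of 527 measured entries in 37 lists of cell type markers and gene functions, 452 were detected.

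Genes of young neurons had the highest levels among the cell type lists. The immature neuron list had a median of 836 TPM (SD of the library medians 5.13, n = 2), with all 12 of its members detected. Stmn1, a regulator of microtubule turnover (chromosome 4, 134468320 to 134473843), was at 1713 ± 16.5 TPM, Tmsb10, which binds actin monomers, at 1458 ± 105 TPM, and Tubb3, the neuronal beta tubulin, at 1272 ± 62.9 TPM. Excitatory neuron genes had a median of 115 TPM (SD 5.31, 12 of 12 detected), led by the calmodulin-binding protein gene Nrgn at 305 ± 6.36 TPM. The vesicular glutamate transporter gene Slc17a7 (ENSMUSG00000070570.5, chromosome 7, 45163949 to 45176142) was at 142 ± 3.63 TPM. Synapse genes had a median of 131 TPM (SD 0.304, 14 of 14), from Syp, a synaptic vesicle protein gene, at 355 ± 1.72 TPM to Bsn, a scaffold gene of the active zone, at 34.1 ± 4.07 TPM.

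Neurons of different cortical layers and the inhibitory neurons were represented as well. Upper layer genes had a median of 66.7 TPM (SD 1.62, 10 of 10), with the transcription factor gene Mef2c at 550 ± 8.06 TPM and Cux2 at 84.2 ± 8.73 TPM. The deep layer list had a median of 27.4 TPM (SD 1.35, 11 of 11), and its member Bcl11b, a transcription factor gene of subcerebral projection neurons, was at 63.4 ± 1.61 TPM. Subplate and Cajal-Retzius genes had a median of 10.5 TPM (SD 2.39, 10 of 11), where Reln, the secreted guide of cortical layering, was at 81.8 ± 4.04 TPM and Lhx5 at 0.780 ± 0.127 TPM. Inhibitory neuron genes had a median of 25.6 TPM (SD 0.463, 12 of 12). Gad1, which encodes a GABA-synthesising enzyme, was at 76.4 ± 8.60 TPM and Nkx2-1, a transcription factor gene of the ventral forebrain, at 1.43 ± 0.134 TPM. In the interneuron subtype list (median 14.5 TPM, SD 1.18, 11 of 12), the neuropeptide genes Sst and Npy were at 159 ± 3.80 and 78.6 ± 1.68 TPM, while Pvalb was at 0.365 ± 0.106 TPM.

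Progenitor, glial and dividing-cell genes spanned a wide range. Radial glia and progenitor genes had a median of 31.1 TPM (SD 3.01, 12 of 12), with the fatty acid binding protein gene Fabp7 at 565 ± 26.8 TPM. Intermediate progenitor genes had a median of 4.14 TPM (SD 0.0707, 5 of 8), and Neurog2 and Neurog1, proneural transcription factor genes, were at 0.270 ± 0.0990 TPM and listed at 0. Cell cycle genes had a median of 6.60 TPM (SD 0.357, 14 of 14), with the proliferation marker Mki67 at 7.76 ± 0.643 TPM. The astrocyte list had a median of 53.0 TPM (SD 3.27, 13 of 13), from the lipoprotein gene Apoe at 344 ± 22.5 TPM to S100b at 2.96 ± 0.346 TPM. Oligodendrocyte precursor genes had a median of 10.5 TPM (SD 1.50, 9 of 10), with Olig1, a transcription factor gene of the lineage, at 47.9 ± 0.368 TPM. Myelinating oligodendrocyte genes had a median of 0.910 TPM (SD 0.152, 5 of 12): Mbp, the myelin basic protein gene, was at 17.0 ± 1.32 TPM, Mog at 0.0800 ± 0.0283 TPM, and Opalin was listed at 0 in both libraries.

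Microglia and macrophage genes had a median of 4.96 TPM (SD 0.774, 14 of 14), with the growth factor receptor gene Csf1r at 12.1 ± 1.59 TPM. Endothelial genes had a median of 8.20 TPM (SD 0.0778, 12 of 12), with the tight junction gene Cldn5 at 40.7 ± 1.75 TPM. Pericyte and smooth muscle genes had a median of 3.67 TPM (SD 0.438, 9 of 10), led by Rgs5 at 35.2 ± 0.212 TPM. Meningeal and fibroblast genes had a median of 20.1 TPM (SD 1.48, 11 of 12), with the prostaglandin D synthase gene Ptgds at 408 ± 41.6 TPM and the growth factor gene Igf2 at 164 ± 8.56 TPM. The choroid plexus and ependyma list had a median of 2.64 TPM (SD 1.85), and the blood list 0.660 TPM (SD 0.0919), with 6 and 4 of 12 members detected. Replicate 1 alone had 11 of the 12 choroid plexus and ependyma members at a TPM of at least 1.

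Among marker lists of other brain regions, striatal genes had a median of 13.0 TPM (SD 1.30, 12 of 12), with the transcription factor gene Foxp1 at 101 ± 5.50 TPM and the dopamine receptor gene Drd2 at 3.09 ± 0.396 TPM. Hippocampal genes had a median of 5.41 TPM (SD 0.392, 7 of 12), led by Zbtb20 at 44.8 ± 2.31 TPM. The list for thalamus and other brain regions had a median of 0.565 TPM (SD 0.120, 5 of 15), with Prkcd at 17.8 ± 2.59 TPM and the hindbrain gene Hoxb3 listed at 0. The list of olfactory bulb and non-brain tissue genes had a median of 0.185 TPM (SD 0.0106, 2 of 12), and the keratin gene Krt5 and the kidney gene Umod were listed at 0. Several genes of these lists, such as Foxp1, also serve cortical neurons, so the lists do not by themselves separate regions.

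Mitochondrially encoded protein genes had the highest median of the 37 lists, 1324 TPM (SD 16.6, 13 of 13), led by mt-Co1, a cytochrome oxidase subunit, at 3690 ± 1.53 TPM. Ribosomal protein genes had a median of 339 TPM (SD 10.6, 22 of 22), with Rplp1 at 1017 ± 25.4 TPM, and nuclear oxidative phosphorylation genes 152 TPM (SD 0.672, 18 of 18), with Atp5b at 686 ± 55.2 TPM. Replication-dependent histone genes had a median of 36.3 TPM (SD 0.919, 27 of 27). Cholesterol synthesis genes had a median of 55.5 TPM (SD 6.45, 17 of 17), led by Hmgcs1 at 405 ± 0.997 TPM. Axon guidance genes had a median of 33.0 TPM (SD 0.544, 18 of 18), with the Slit receptor gene Robo2 at 108 ± 2.47 TPM, and ion channel and transmitter receptor genes 37.9 TPM (SD 0.824, 21 of 22), with the AMPA receptor gene Gria2 at 177 ± 27.4 TPM. Stress and heat shock genes had a median of 18.0 TPM (SD 1.03, 14 of 16), led by the chaperone gene Hspa8 at 1009 ± 5.18 TPM. Immediate early genes had a median of 5.25 TPM (SD 0.541, 13 of 14), with the transcription factor gene Fosl2 at 25.0 ± 1.202 TPM, and interferon response genes 0.393 TPM (SD 0.0424, 4 of 14), with Ifi27 at 8.87 ± 0.940 TPM. Some levels depended on the table, in genes picked after their values were seen: Hist2h2aa1 was at 4.50 TPM in the first table and 504 in the second, Rpl10 at 135 and 869, Cycs at 16.8 and 178, and mt-Co2 at 121 and 1111.

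Sex-linked and imprinted genes were measured next. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), was at 139 ± 26.9 TPM, and the sex-linked list had a median of 2.99 TPM (SD 0.350, 7 of 14). The Y-linked genes Zfy1 and Sry were listed at 0 counts in both libraries. All 31 imprinted genes were detected, with a median of 31.4 TPM (SD 1.97). Meg3, a maternally expressed lincRNA (ENSMUSG00000021268.17, chromosome 12, 109541001 to 109571726), was at 1176 ± 278 TPM, Nnat at 927 ± 37.0 TPM, Rian at 855 ± 106 TPM and Gnas at 846 ± 18.5 TPM. At the low end were Dlk1, the paternally expressed neighbour of Meg3, at 2.84 ± 0.757 TPM and Kcnq1ot1 at 2.61 ± 1.22 TPM. The nuclear-retained and structured noncoding RNA list had a median of 158 TPM (SD 36.6, 15 of 15), and the telomerase RNA gene Terc and Neat1, the scaffold of paraspeckles, were at 6.46 ± 1.49 and 4.65 ± 1.02 TPM. Reads were not assigned to the C57BL/6J or CAST/EiJ allele, so parental expression was not measured here.

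**Figure D1:**
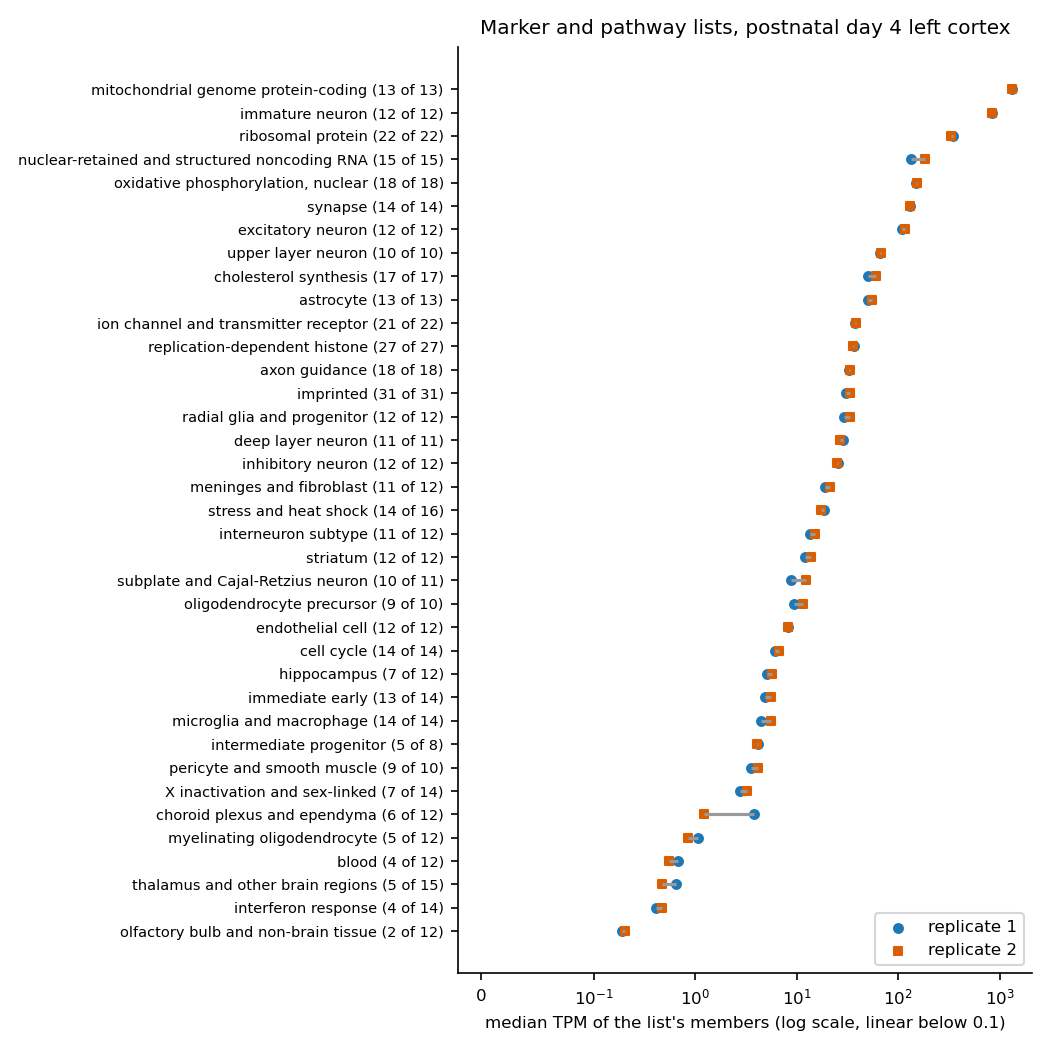
Median TPM of each of the 37 lists in replicate 1 (circles) and replicate 2 (squares), on an axis that is logarithmic above 0.1 and linear below, with the members detected in both libraries out of those measured beside each name. The lists run from mitochondrially encoded genes at 1324 TPM to olfactory bulb and non-brain genes at 0.185 TPM, and the choroid plexus and ependyma list lies at 3.83 TPM in replicate 1 and 1.21 TPM in replicate 2.

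Pairs of genes whose balance shifts during brain development were compared within each library, as the log2 ratio of TPM + 1. Slc12a5, the chloride exporter of mature neurons (ENSMUSG00000017740.17, chromosome 2, 164960802 to 164999731), was above Slc12a2, the chloride importer, with a log2 ratio of -2.47 ± 0.01 (SD, n = 2) for Slc12a2 over Slc12a5. Among glutamate receptor subunits, Grin2b exceeded Grin2a by 2.54 ± 0.08. The glutamate transporter Slc17a7 exceeded Slc17a6 by 2.25 ± 0.01, and the young-neuron gene Dcx exceeded the mature-neuron gene Rbfox3 by 1.80 ± 0.01. Gad1 exceeded Gad2 by 1.69 ± 0.13, Sst exceeded Pvalb by 6.88 ± 0.15, and Dlg3 over Dlg4, both postsynaptic scaffolds, was -2.44 ± 0.17. Of the kinase subunits, Camk2b exceeded Camk2a by 1.38 ± 0.15. The neurofilament gene Nefm exceeded Nefh by 3.35 ± 0.17, and Tuba1a exceeded Tuba4a by 6.23 ± 0.06.

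Glial and regulatory pairs were apart too. Nes over Gfap was -1.08 ± 0.04, Fabp7 exceeded Aldh1l1 by 4.19 ± 0.02, and the precursor receptor gene Pdgfra exceeded the myelin gene Mog by 4.96 ± 0.05. The splicing regulator Ptbp2 exceeded Ptbp1 by 1.53 ± 0.09, and the DNA methyltransferase Dnmt3a exceeded Dnmt3b by 5.23 ± 0.15. Xist exceeded its antisense partner Tsix by 6.74 ± 0.09 and Meg3 exceeded Dlk1 by 8.26 ± 0.63. The adult globin gene Hbb-bs was at 153 TPM in replicate 1 and 20.3 TPM in replicate 2, while the embryonic Hbb-bh1 was listed at 0 counts in both, so no ratio is given. In all, 18 of the 22 pairs, this one included, reached a log2 ratio of at least 1 in size with the same sign in both libraries. Among those that did not were Slc17a7 over Gad1 at 0.89 ± 0.12 and Pdgfra over Mbp at 0.90 ± 0.19. Pdgfra over Mbp reached 1.03 in replicate 2 alone, and Slc17a7 over Gad1 was 1.29 in the second table. Ratios against a gene near or below 1 TPM depended on the pseudocount: with 0.1 in place of 1, Pdgfra over Mog was 7.51, Xist over Tsix 8.49, Sst over Pvalb 8.44 and Dnmt3a over Dnmt3b 5.85. In the second table Ptbp2 over Ptbp1 was 2.30, Meg3 over Dlk1 7.49 and Tuba1a over Tuba4a 5.58. An exact sign-flip test over 2 libraries cannot give a p below 0.5, so none was run.

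**Figure D2:**
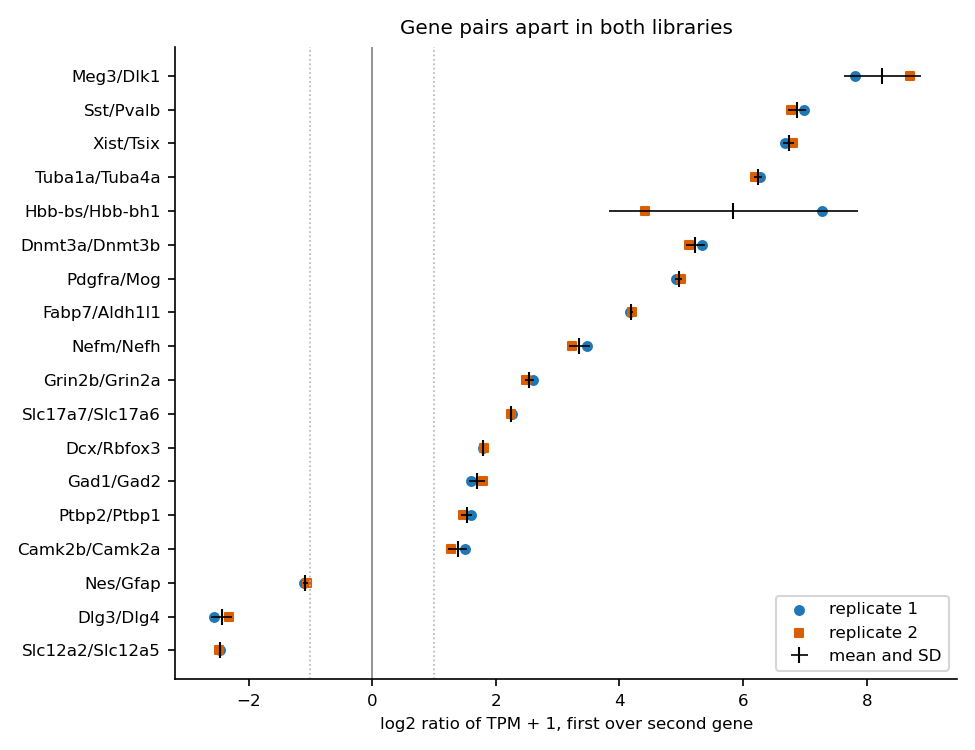
Log2 ratio of TPM + 1 of the first over the second gene of each of the 18 pairs that reached 1 in size in both libraries, for replicate 1 (circles), replicate 2 (squares) and their mean with SD (black), with dotted lines at -1 and 1. Each pair lies beyond the same dotted line in both libraries, and the Hbb-bs/Hbb-bh1 pair, whose second gene is listed at 0, is spread most widely.

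Dominant transcripts were called for genes with several annotated transcripts. Mapt-204, a transcript of the tau gene with 10 exons and 1116 coding bases (chromosome 11, 104231390 to 104332090), took 93.4% ± 1.30 of the gene's TPM (SD, n = 2). App-201, of the amyloid precursor gene (16 exons, 2085 coding bases), took 89.3% ± 0.678, and Xist-201 85.1% ± 0.0714. Camk2b-209 took 75.9% ± 0.590, Rtn4-205 72.6% ± 3.95 and Stmn2-201 72.1% ± 0.457. Tubb3-201 took 100% of the gene's TPM. Between 60 and 70% were Cltb-201 (68.4% ± 2.20), Cdc42-201 (66.6% ± 0.508), Bin1-201 (65.9% ± 1.15), Clta-204 (65.9% ± 0.558), Src-202 (62.5% ± 0.575) and Dcx-201 (62.2% ± 0.696). Below these lay Snap25-201 (57.5% ± 0.984), Gnas-208 (56.5% ± 0.136), Nfasc-202 (56.2% ± 2.55), Mbp-205 (53.7% ± 3.92) and Tpm3-201 (50.8% ± 0.911).

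The dominant transcripts of these genes were also those of the second table, but some had quite different shares there: 72.7% for Mapt-204, 49.3% for Rtn4-205, 42.1% for Src-202, 43.8% for Nfasc-202 and 99.2% for Stmn2-201. Of the 40 genes chosen for known splicing in brain, 33 had the same dominant transcript in every table and 4 differed between the libraries. Of those 4, Dlg4, Ptbp2 and Kif2a also had different leading transcripts in the first and second tables. Kif2a-205 took 28.3% in the first table and 0% in the second, where Kif2a-204 took 55.8%. The other 3 of the 40 were the same between the libraries but differed between the tables. Each transcript is given with its share in the table where it dominated: Nrcam-201 (19.2% ± 0.0497) against Nrcam-204 (22.0% ± 0.390), Dnm1-203 (24.5% ± 3.28) against Dnm1-205 (27.8% ± 2.496), and Dclk1-201 (26.4% ± 1.96) against Dclk1-204 (40.9% ± 2.95). Over 12379 genes with several transcripts, the dominant one was the same in both libraries for 87.7% in the first table and 85.8% in the second. It was the same in all 4 library tables for 8100 genes (65.4%), and 1615 genes had 1 dominant transcript within each table but a different one between them.

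Across 15304 genes detected in both libraries, log2(TPM + 1) correlated with a Pearson r of 0.991 and a Spearman rho of 0.990. This correlation is across genes, which are not independent replicates. The log2 ratio of TPM + 1, replicate 2 over replicate 1, had a median of 0.06 and an SD of 0.24. By that ratio 78.6% of the genes lay within 1.2-fold, and 76 differed by 2-fold or more. The added 1 makes ratios smaller for genes at a few TPM, so these figures are not folds of TPM. Within 1.2-fold by that ratio were 63.2% of genes at a mean TPM of 1 to 5 and 96.3% at 100 or more. The common biological coefficient of variation estimated by edgeR was 0.0936 over 17742 genes. Spike-in RNAs took 0.330% and 0.346% of the expected counts, 59 of 96 were detected in both libraries, and their levels correlated across spike-ins with r = 0.998. The libraries were not copies of 1 library, since 4421 genes differed beyond counting error at an exact binomial adjusted p under 0.05.

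**Figure D3:**
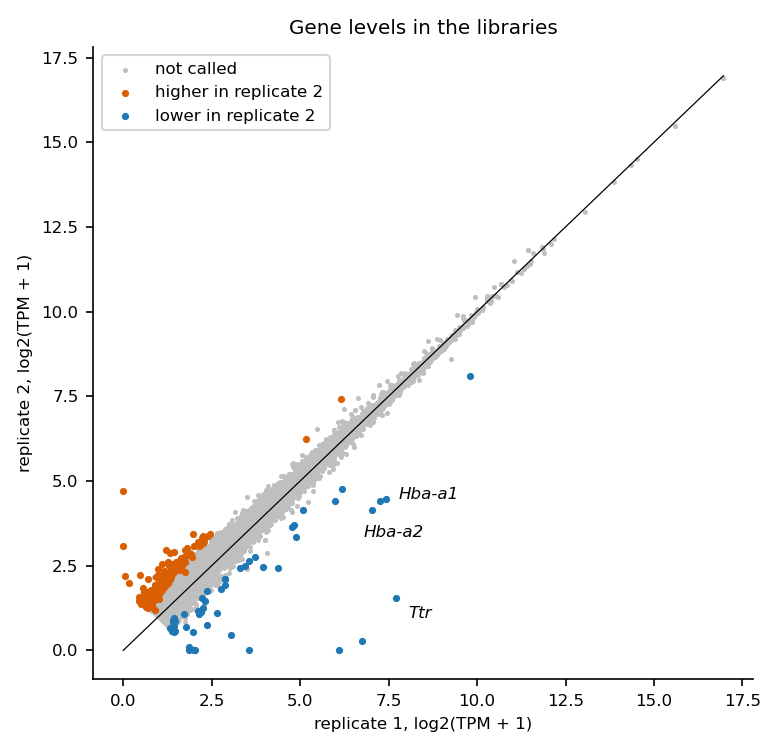
Log2(TPM + 1) of each tested gene with a mean TPM of at least 1, replicate 1 on the x axis and replicate 2 on the y axis, with the line of equal levels; orange and blue points passed the exact binomial test with a log2 ratio of at least 1 in size. Ttr, Hba-a1 and Hba-a2 lie far below the line.

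Blood and choroid plexus genes were lower in replicate 2 than in replicate 1 as sets, and 5 of 6 tested blood members and 6 of 12 tested choroid plexus and ependyma members were called singly. The blood list had a median log2 ratio of -2.85 (lower in 5 of 5 members with a mean TPM of at least 1). Its adult haemoglobin genes Hba-a1 (chromosome 11, 32283511 to 32284465) and Hbb-bs (chromosome 7, 103826534 to 103828096) were at 171 and 153 TPM in replicate 1 and 20.9 and 20.3 TPM in replicate 2. Hba-a2, Hbb-bt and Alas2, the first enzyme of haem synthesis in red cell precursors, were lower too, with log2 count ratios of -3.02, -2.25 and -2.38. Alpha globin counts summed to 3078 and 370 and beta globin counts to 1785 and 248, so the difference did not depend on how reads were split between near-identical globin copies. The choroid plexus and ependyma list had a median of -0.73 (8 of 8 lower). Ttr, the thyroid hormone carrier made by choroid plexus epithelium (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), was at 206 and 1.94 TPM.

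Of the other choroid plexus and ependyma members, Kcne2 had 47 and 2 counts, 23.6-fold lower in replicate 2 with a counting interval of 6.19 to 201. Otx2 had a log2 count ratio of -2.88, Folr1 -1.89, Clic6 -1.69 and Ccdc153, a gene of ciliated cells, -1.15. Of the members not called, Enpp2 was at 25.2 and 21.6 TPM, Foxj1, the regulator of motile cilia, at 5.81 and 3.30 TPM, Rarres2 at 4.88 and 3.44 TPM, and Sostdc1 at 3.67 and 2.48 TPM. Ccdc153, Folr1 and Clic6 lost their calls in the edgeR exact test with the trended dispersion, and Ccdc153 had a log2 count ratio of -0.56 with counts from the second table.

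**Figure D4:**
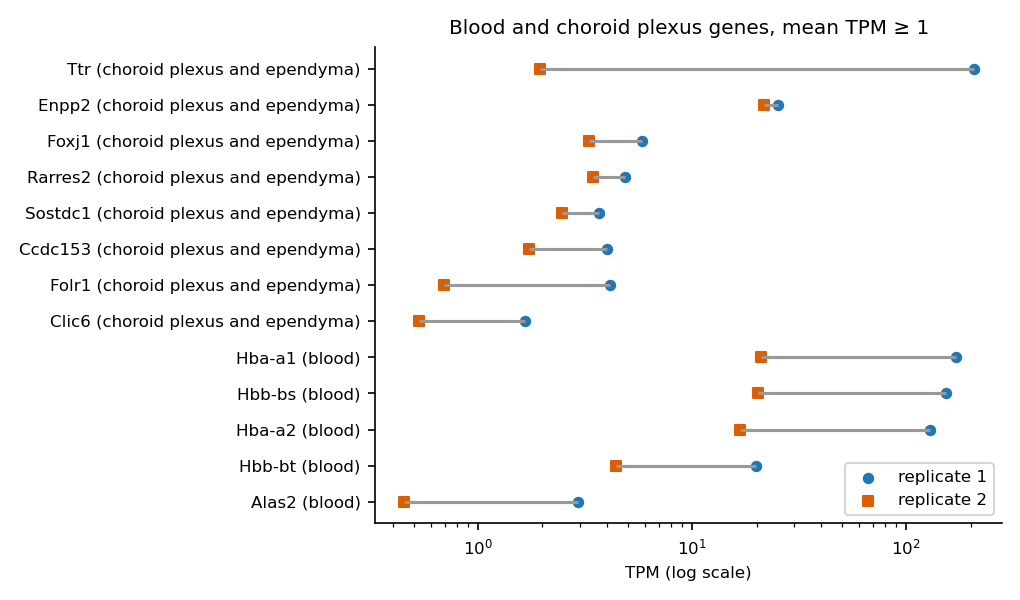
TPM on a log axis of blood and choroid plexus and ependyma list members with a mean TPM of at least 1, replicate 1 as circles and replicate 2 as squares. All members shown (8 of choroid plexus and ependyma, 5 of blood) lie lower in replicate 2, from Ttr at 206 against 1.94 TPM to Enpp2 at 25.2 against 21.6 TPM.

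Smaller shifts were found for ribosomal protein genes (median log2 ratio -0.10, 21 of 22 lower in replicate 2) and replication-dependent histone genes (-0.11, 21 of 27 lower). Rplp1 and Rpsa were at 1017 ± 25.4 and 510 ± 21.1 TPM, and Hist2h3b and Hist1h1c at 139 ± 8.07 and 91.1 ± 12.2 TPM. Removing the trend with transcript length, a choice made after seeing the data, ended these calls, although the medians were then -0.10 in both lists. The matched random lists moved down, from a median of -0.03 (95% range -0.07 to 0.02) to -0.08 (-0.11 to -0.04) for ribosomal proteins (permutation adjusted p 0.324), and from 0.04 (-0.02 to 0.12) to -0.03 (-0.08 to 0.04) for histones (permutation adjusted p 0.0655). With the trend with GC content removed, ribosomal proteins had -0.14 against -0.09 (-0.13 to -0.04) in the random lists, with a permutation adjusted p of 0.0825. The list of olfactory bulb and non-brain tissue genes had a median of -0.76 over 3 members. The cardiac myosin gene Myh6 was at 2.97 and 1.34 TPM, the skeletal actin gene Acta1 at 2.68 and 2.73 TPM, and Eomes, a transcription factor gene that the intermediate progenitor list also holds (chromosome 9, 118478212 to 118486132), at 2.44 and 0.610 TPM. These members belong to different tissues, and Eomes was the one called singly, with a log2 count ratio of -2.14 (155 and 35 counts).

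Each list's median was set against 10000 random lists of the same size matched on mean expression, two-sided. Genes were drawn singly and no libraries were permuted. The permutation p therefore treats the members of a list as independent and measures no spread between animals. The Benjamini-Hochberg adjusted permutation p over the 37 lists was 0.00247 for blood, for choroid plexus and ependyma and for histones, which rest on the smallest unadjusted p that the random lists can give, 0.0002. It was 0.00740 for ribosomal proteins and 0.0266 for olfactory bulb and non-brain genes. These 5 lists were called and 12 had an unadjusted p under 0.05. The intermediate progenitor list, with a median of -0.17 (5 of 6 lower), missed the threshold with an adjusted p of 0.0506. The nuclear-retained and structured noncoding RNA list had 0.11 (9 of 15 higher, adjusted p 0.0641), and a median of 0.33 with an adjusted p of 0.00247 in the second table.

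Single genes were compared between the libraries by an exact conditional binomial test on rounded expected counts, which compares these libraries and not conditions. Oc90, a protein gene of the otoconia of the inner ear (ENSMUSG00000015001.17, chromosome 15, 65876053 to 65912397), had 1 count in replicate 1 and 97 in replicate 2, a ratio of 96.5 with a counting interval of 16.9 to 3851. Ttr had 4357 and 39 counts, 112-fold lower in replicate 2 with an interval of 82.0 to 158. Tspan10 (chromosome 11, 120442644 to 120446950) had 220 and 11 counts, 20.1-fold lower with an interval of 11.0 to 40.9. The TEC loci Gm42441, Gm42639 and 9430087J23Rik were 8.76-fold (3.48 to 28.3), 4.88-fold (3.07 to 8.12) and 4.23-fold (1.92 to 10.6) higher in replicate 2. The adjusted p was 1.54e-25 for Oc90 and 2.96e-49 for Tspan10 by that exact test with Benjamini-Hochberg adjustment over the genes tested.

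Processed pseudogenes made up most of the other extreme differences. Gm10163 had 786 counts in replicate 1 and 1 in replicate 2, a ratio of 790 with an interval of 141 to 31243. Rnu3a, a copy of the U3 small nucleolar RNA gene, had 151 and 0 counts. Against a floor of 3 counts per library it was 50.6-fold lower in replicate 2 (exact lower limit 40.6). Against the same floor, Gm10132 was 25.8-fold lower (exact lower limit 20.5) and Gm10145 7.04-fold (5.23). Gm14434, Gm20521 and Gm49325, annotated as protein-coding, were 20.4-fold (16.1), 19.4-fold (15.3) and 8.04-fold (6.05) lower. Gm10232 had 32 and 1 counts, a ratio of 32.2 (5.37 to 1310). In the other direction, against that floor, the misc_RNA gene Gm27624 was 12.3-fold higher in replicate 2 (exact lower limit 9.49) and Smt3h2-ps4 8.62-fold higher (6.53). The posterior SDs of the counts of 0 set against that floor ran from 5.92 in Gm27624 to 65.9 in Rnu3a. All were above the floor of 3 counts, which covers counting error only. Gm29214 had 1 and 26 counts (ratio 25.9, interval 4.25 to 1061), and Gm18875, Gm8185 and Gm12191 were 5.26-fold, 5.22-fold and 5.14-fold higher. The second table listed Gm27624, Smt3h2-ps4, Gm12191, Rnu3a, Gm10132, Gm10145 and Gm10232 at 0 in both libraries, and Gm10163, whose posterior SDs of the count were 381 and 234 in the first table, at 3.11e-06 and 0 TPM. It gave Gm14434 12.5 and 5.40 TPM, Gm20521 1.99 and 0.618 TPM, Gm49325 14.7 and 9.79 TPM and Gm29214 a log2 count ratio of 2.22 against 4.14 in the first table, so these counts and bounds are uncertain. Gm18875, Gm12191, Gm8185 and 9430087J23Rik also lost their calls in the edgeR exact test.

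Of 18492 genes tested, 532 (2.88%) passed an adjusted p of 0.05 with a log2 ratio of at least 1 in size, 441 higher and 91 lower in replicate 2. At a mean TPM of at least 1 there were 301, of which 248 were higher and 53 lower. Called were 298 of 1393 tested TEC loci (21.4%), 26 of 155 sense intronic genes (16.8%), 3 of 21 misc_RNA genes (14.3%), 8 of 72 transcribed processed pseudogenes (11.1%) and 51 of 665 processed pseudogenes (7.67%), against 108 of 14701 protein-coding genes (0.735%). All 324 called TEC and sense intronic genes were higher in replicate 2. Of 1179 such loci inside introns of an expressed gene on the same strand, 302 were called and the median log2 count ratio was 0.81. Outside protein-coding genes, the median was 0.41 over 229 loci, and over 45 loci overlapping exons it was 0.44. The 95 loci antisense to, or inside, a gene under the TPM minimum had a median of 0.04, with 1 called. Of the 37 lists fixed in advance, 6 had a called member and 31 had none, with 15 calls among 492 tested entries over all genes tested and 16 adjusted over the list alone. Besides the blood and choroid plexus genes and Eomes, which 2 lists hold, the called members were Tsix (log2 count ratio 1.22, exact binomial adjusted p 0.0435), which lost its call in the edgeR exact test, and mt-Co2 (1.22), whose ratio was -0.17 with counts from the second table. With a dispersion from edgeR in place of counting error alone, 83 genes passed, 46 higher and 37 lower, all among the 532. That dispersion was estimated from these same libraries, so the differences under test also set it. It makes the test stricter on the same counts, so the overlap with the 532 is no separate support.

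Gene levels of the quantifiers were compared over 15294 genes, with both libraries averaged. Protein-coding genes correlated across genes with r = 0.969 (13127 genes), while the other biotypes gave r = 0.250 (2167 genes). In 528 genes the level in the second table was under 0.1 times that in the first. Rn7s1 was at 0.717 TPM and Rn7sk at 0 in the second table, and Snurf, an imprinted gene that shares its transcript with Snrpn and was chosen after its values were seen, was at 603 TPM in the first table and at 0 in the second.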

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

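No test was run in this part; it gives values only. Entries with a number in place of a gene identifier, which no comparison used, held 4.98 expected counts in replicate 1 and 12 in replicate 2, above the 3 counts that a count of 0 allows. They are 26248 entries with at most 4 counts each, and they were not matched to any sequence here.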

How the results depend on the processing

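Chosen only after the result was seen were the removal of trends with transcript length and GC content, random lists from protein-coding genes, the comparison without TEC and sense intronic genes, and counts from the second table. No paired analysis was possible because the series has 1 group. Detected genes ranged from 11097 to 17276 over the alternatives (15719 and 16420 with 1 library left out), detected list members from 383 to 462 (453 and 462) and pairs apart from 18 to 20 (18 and 20).

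The Pearson r between libraries was 0.989 with a pseudocount of 0.1, 0.993 with no filter and 0.989 in the second table. The coefficient of variation was 0.0938 with DESeq2 size factors and 0.0986 with no filter. The 532 genes differing became 537 with DESeq2 size factors, 509 with spike-in scaling and 561 with a summed count of at least 1. They became 4421 (2343 higher, 2078 lower) with no minimum ratio and 83 (46 and 37) in the edgeR exact test. That test adds a dispersion, estimated from these same libraries, to counting error. Without TEC and sense intronic genes 208 remained, 117 higher, because those genes were removed. With counts from the second table there were 750, 673 higher, of which 310 were among the 532, and mt-Co2 reversed to -0.17; the cause was not tested.

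The 5 lists called became 8 in the second table, 4 with the length trend removed, 5 with the GC trend removed, 6 against random lists from protein-coding genes and 3 at a mean TPM of at least 5, where the choroid plexus and olfactory lists had under 3 members and gave no value. With the length trend removed the histone list had -0.10 (adjusted p 0.0655, against 0.00180 to 0.0211 under its other alternatives) and the ribosomal list -0.10 (adjusted p 0.324). With the GC trend removed the ribosomal list had -0.14 (adjusted p 0.0825), and its other alternatives gave 0.00432 to 0.0163. The list of mitochondrially encoded genes, near 0 before (adjusted p 0.482), gained a call with the GC trend removed (-0.25, adjusted p 0.00185; 0.2 to 0.945 under its other alternatives). Calls were also gained by the nuclear-retained RNA list with the length trend removed (0.07, adjusted p 0.0247) and in the second table (0.33, adjusted p 0.00247), by nuclear oxidative phosphorylation against protein-coding random lists (-0.07, adjusted p 0.0480), and in the second table by the myelinating oligodendrocyte (-0.19, adjusted p 0.0211) and stress lists (-0.11, adjusted p 0.0213). The cause was not tested. The blood list kept its call under each of the 6 alternatives, from -2.91 to -2.39, and the choroid plexus list under each of the 5 that gave a value, from -0.98 to -0.73.

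Dominant transcripts were the same in all tables for 69.0% of genes at a TPM of at least 10 and 92.5% where the first exceeded the next 2 times, against 91.8% and 99.2% between libraries in the first table and 89.9% and 98.96% in the second; fewer genes were compared in each. By TPM, nuclear protein-coding genes held 50.8% and misc_RNA 29.9%, since TPM divides by length. At an expected count of at least 10, 39 spike-ins were detected. List differences, agreement and the gene comparison need both libraries, so no library could be left out of them.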

Other observations

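Tubulin and actin genes made up 6 of the 10 most abundant nuclear protein-coding genes, which were listed after their values were seen. Tuba1a was followed by Actb at 2792 ± 114 TPM, the translation factor gene Eef1a1 at 2652 ± 94.3 TPM, Tubb2b at 1981 ± 66.1 TPM and Actg1 at 1799 ± 59.6 TPM (SD, n = 2). Tubb2a was at 1443 ± 62.0 TPM and Tubb5 at 1319 ± 52.5 TPM.

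In the patterns weighed next, the tests of depth or scaling, of globin copies and of fragment length were chosen only after the result was seen; the tests of further markers, unspliced RNA, genomic DNA and shared reads were written after the pattern was seen but before their own values were.

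Blood and choroid plexus genes were lower in replicate 2, with list medians of -2.85 and -0.73. A factor shared by all genes would have moved random lists of the same level as well, but in the list comparison itself, not a separate test, the list nearer to 0 differed from them by -0.825 (95% range of their medians -0.07 to 0.31), and the smaller of the summed alpha and beta globin folds was 7.23, which argues against depth or scaling and against reads shared between globin copies. Of 17 further choroid plexus genes, 12 could be measured at a mean TPM under 5 and 10 were lower (median -1.11; Cldn2 -2.81, Aqp1 -1.12, Prlr 0.14), in line with more choroid plexus tissue in the sample of replicate 1, where Ttr was at 206 against 1.94 TPM; 3 more, Sulf1, Slc4a2 and Cab39l, the tissue expresses above that limit. Of 24 further erythroid genes, 3 could be measured (Tspan33 -0.18, Tal1 -0.49, Gypc 0.04; median -0.18) and 7 the tissue expresses above the limit, so residual blood could be neither favoured nor set aside, although Hba-a1 was at 171 against 20.9 TPM. Why Ttr fell by more than the other choroid plexus genes is left open, and a difference between the animals was not tested.

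TEC and sense intronic genes were higher in replicate 2. Their median log2 count ratio was 0.73 above that of protein-coding genes matched on summed count, whose random lists reached 0.03. A shared factor would have moved those random lists as well. These values argue against depth or scaling, though they restate the pattern already seen and are no separate test. Olfactory receptor genes had 0.135 counts per kilobase in replicate 2 (upper 95% limit 0.151), 0.0183 of the median increase of 7.42 per kilobase, which argues against genomic DNA. Loci inside introns of expressed genes on the same strand exceeded loci outside protein-coding genes by 0.40 (bootstrap interval over loci 0.33 to 0.53). The bootstrap treated loci as independent and covers no spread between libraries or animals. A larger share of unspliced RNA in replicate 2 may therefore account for part of the pattern. The median of 0.41 outside protein-coding genes is left open, beside 0.04 over loci antisense to, or inside, a gene under the TPM minimum, as is a difference between the animals, which was not tested.

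Short RNAs were near 0 in the second table. Of 8867 genes at a TPM of at least 10 in the first table, 256 had a level under 0.1 times as high in the second, and 164 of the 165 genes with no transcript longer than the fragment length of the second table (352 and 351 bases) were among them. Short genes made up 64.1% of the 256, which leaves 92 longer ones and falls short of the 80% set for fragment length as the whole cause. The posterior SD over the square root of the count had a median of 0.959 in the 256 genes against 0 in the others. That lies below the 1 set for shared reads. Low levels went with length: 40 of 41 genes with a longest transcript over 250 and up to 350 bases were under 0.1 times as high. Just above the fragment length, over 350 and up to 500 bases, 53 of 112 were, with a median ratio of 0.142. Over 2000 bases, 2 of 6924 were. Shared reads were not compared among genes of the same length. Their part in the short genes, and the cause in the 92 longer ones, therefore cannot be told here. No biological explanation was tested.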
